A study of Mus musculus with 58 samples.

How the data were processed

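RNA of the tibialis anterior and the diaphragm of NSG mice was labelled with biotin and hybridised to Affymetrix arrays, per the labels. The deposited table holds log2 expression values of 25206 probe sets on 58 arrays, which the authors computed with RMA (background correction, quantile normalization and a summary over the probes of each set) in the R package affy 1.36.1 under R 2.15.1, per the submitters' processing notes. That the values are on the log2 scale was read from the values, whose array medians lay between 3.702 and 3.862 and whose highest values lay between 11.73 and 12.6. The probe set definitions, the genome build and whether the cohorts were normalized together are not given in the sources used here. The table held 0 columns of other series. The highest correlation between any 2 arrays was 0.993, and no pair of arrays held identical values.

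Probe sets were named through the Entrez gene numbers of the platform annotation. Of the 25206 probe sets, 23185 had a gene symbol and 2021 had none, and each symbol had 1 probe set. All 23185 numbers were found in the gene table and 0 symbols needed an update. The 23185 named genes were tested, with no filter on dim genes. The number of arrays limits the precision of a comparison, and no depth applies.

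Groups were taken from the labels: muscle, cohort and sham or PDX, which makes 16 groups. The labels name sham and tumour-bearing animals and give a number to each sample, but they do not state that every array comes from a separate animal or that equally numbered samples of both muscles come from the same mouse. The p-values measure the spread between these samples.

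Tests were run in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Each muscle was fitted on its own with a mean per cohort and treatment, and the tumour effect was the mean over the 4 cohorts, equally weighted, of PDX minus sham. The difference of this effect between muscles (diaphragm effect minus tibialis anterior effect) and the difference between the sham muscles were taken from a fit of all 58 arrays with 16 group means. Cohort effects came from the muscle fits, and a moderated F test asked whether the 4 cohort effects differed. A gene passed with a Benjamini-Hochberg adjusted p under 0.05 from limma, two-sided, over all 23185 genes. Standard errors are limma's moderated errors of the log2 difference.

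A total of 41 gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 41 lists within a comparison, with counts of members adjusted over all genes and adjusted over the list alone. The lists were atrophy genes, autophagy and lysosome, proteasome subunits, immunoproteasome and antigen presentation, glucocorticoid-responsive genes, STAT3 and acute-phase genes, NF-kB and cytokine genes, complement, type I interferon response, fibrillar collagens and matrix, basement membrane, matrix proteases and inhibitors, and TGF-beta, myostatin and activin signalling. Cell type lists covered fibro-adipogenic progenitors and fibroblasts, macrophages and monocytes, neutrophils, lymphocytes, endothelium, adipocytes, mesothelium, hepatocytes and pancreatic acinar cells, erythroid cells, Schwann cells and nerve, and pericytes and smooth muscle. The remaining lists were satellite cell and regeneration genes, denervation and neuromuscular junction genes, fast sarcomere genes, slow sarcomere genes, dystrophin complex and costamere, glycolysis and glycogen, oxidative phosphorylation, the TCA cycle, fatty acid oxidation and uptake, mitochondrial biogenesis and dynamics, cytosolic ribosomal proteins, ER stress and amino acid response, amino acid and polyamine metabolism, the circadian clock, the cell cycle, oxidative stress and metal response, and insulin and IGF signalling. Members of a list without a named probe set were not analysed here. Each list test was repeated with a correlation estimated from the data and with fry, which asks whether the members move, on balance, one way. With the estimated correlation, 5 of the 21 lists that passed in the tibialis anterior held, 3 of 23 in the diaphragm, 9 of 22 in the difference between the muscles and 8 of 25 in the sham muscles.

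The groups, tests, gene lists, the rule for the genes named in the text and most alternatives were fixed before the data were examined. The rule took, for each muscle, the 10 genes with the highest and the 10 with the lowest log2 difference among those that passed with the same sign in all 4 cohorts. For the difference between the muscles and for the sham muscles it took the 8 highest and the 8 lowest, and for the cohort differences the 5 smallest F-test p-values per muscle. From each list it took up to 4 members with the largest absolute difference past the threshold, or the 2 with the smallest p where none passed, and not every gene so chosen is printed. In both muscles it also took Fbxo32, Trim63, Foxo1, Cebpd, Mstn, Ppargc1a, Col1a1, Col3a1, Igf1, Myh4 and Myh7. Predicted genes, olfactory and vomeronasal receptors, names ending in Rik or starting with Gm, microRNA, snoRNA and pseudogenes were counted but passed over in the first 3 parts of the rule. Outside the rule stands Mir1192, chosen after its values were seen to complete a count of 3.

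Fits were tested on simulated arrays with the data's spreads and 200 changed genes, 100 by 1.5-fold and 100 by 2-fold. Of the 1.5-fold and 2-fold changes, 93% and 99% passed in the tibialis anterior and 89% and 96% in the diaphragm. In the difference 73% and 96% did. False calls were 7, 15 and 7 of 23185. Permuted labels gave up to 1713 in the tibialis anterior alone, so real error can be higher.

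Agreement between the muscles was set against 100 permutations of the treatment labels within cohorts, in which equally numbered samples of both muscles were permuted together. Alternatives covered trended and robust variances, a filter at the median of all probe sets (3.79), a further quantile normalization, array weights, a 1.5-fold threshold, an additive model, the cohort as the replicate, the replicate number as a random block, each array and each cohort left out in turn, all probe sets with a symbol, Spearman's correlation, an estimated correlation between genes and fry. Alternatives chosen after seeing the data used the hepatocyte list mean, the array upper quartile or the mean of 5 tendon genes per array as a covariate, left out the diaphragm arrays with hepatocyte transcripts, or left out 3 tibialis anterior arrays of cohort 3 that stood apart from their groups.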

Results

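Gene expression was measured in the tibialis anterior, a muscle of the lower leg, and in the diaphragm, the main muscle of breathing, of NSG mice, an immunodeficient strain that accepts human tissue. In the tumour-bearing mice, pieces of human pancreatic ductal adenocarcinoma were grown on the pancreas as patient-derived xenografts (PDX), and the mice developed cachexia, a wasting of muscle and fat. Sham mice had the operation alone. Tumours of 4 patients gave 4 cohorts of mice, each with its own sham group. Each muscle was represented by 12 sham and 17 PDX arrays. Every cohort had 3 sham arrays per muscle, and cohorts 1, 2, 3 and 4 had 3, 5, 5 and 4 PDX arrays per muscle. Median log2 signals of the arrays lay between 3.702 and 3.862. Where a group mean lay below the median of all probe sets (3.79), a difference is read as a lower bound: such genes include Kera, Tnmd and Postn in the tibialis anterior, Chl1, Ccl8, Ms4a7, Timp1, Mcpt4, Top2a and Mki67 in the diaphragm and Myh7, Pkhd1l1, Tecrl, Hoxc10, Mettl11b and Sim1 between the sham muscles.

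In the tibialis anterior, PDX mice had higher levels of stress-hormone and acute-phase genes than sham mice and lower levels of collagen genes. With a correlation between genes estimated from the data, the acute-phase list lost its call (adjusted p = 0.166) and the glucocorticoid and matrix lists kept theirs. Lcn2, the acute-phase protein lipocalin 2, rose by 2.87 on the log2 scale (7.30-fold, SE 0.47, 17 PDX and 12 sham arrays, adjusted p = 0.000109). Fkbp5, a co-chaperone that glucocorticoids induce, rose by 1.86 (3.63-fold, SE 0.23, adjusted p = 3.12e-06). The muscle ubiquitin ligases Fbxo32 (atrogin-1) and Trim63 (MuRF1) rose 1.68-fold (log2 0.75, SE 0.12, adjusted p = 5.88e-05) and 1.89-fold (log2 0.91, SE 0.15, adjusted p = 0.000121). Col1a1, which encodes a chain of type I collagen, changed by a log2 difference of -2.55 (0.171-fold, SE 0.15, adjusted p = 3.14e-11), with cohort values of -3.44, -1.39, -2.85 and -2.53.

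Further genes with the largest increases in the tibialis anterior were the metallothionein genes Mt2 and Mt1 with log2 differences of 2.50 (SE 0.32) and 1.75 (SE 0.22), and Serpina3n with 2.01 (SE 0.40, adjusted p = 0.000906). Ddit4, an inhibitor of mTORC1 signalling, rose by 1.90 (SE 0.27), Il6ra, a receptor of interleukin 6, by 1.67 (SE 0.22), and the transcription factor gene Cebpd by 1.64 (SE 0.22). Cep85l rose by 1.61 (SE 0.15) and Depp1, a FoxO target, by 1.48 (SE 0.22). Among the genes with the largest decreases, Ighm, the immunoglobulin mu heavy chain, had a log2 difference of -3.08 (0.118-fold, SE 0.27, adjusted p = 3.14e-08). The tendon and cartilage genes Kera, Chad, Fmod and Tnmd had differences of -2.23 (SE 0.19), -2.03 (SE 0.27), -1.64 (SE 0.21) and -1.58 (SE 0.13). Col1a2 and Col3a1 had differences of -1.99 (SE 0.14) and -1.89 (SE 0.14), Ostn, the secreted peptide musclin, of -1.91 (SE 0.26), and Cyfip2 of -1.59 (SE 0.18). All of these genes had the same sign in the 4 cohorts. Foxo1, a transcription factor of the atrophy programme, rose by 0.79 (adjusted p = 0.000544) and Igf1, a muscle growth factor, fell by 0.40 (SE 0.10, adjusted p = 0.00613). Mstn (0.21, adjusted p = 0.304), Ppargc1a (-0.23, adjusted p = 0.561) and Myh7 (-0.20, adjusted p = 0.443) did not pass. Myh4, the fastest myosin heavy chain, had 0.13 (adjusted p = 0.038) at mean levels of 11.99 and 12.12, near the highest signals of these arrays (11.84 to 12.24), where a change can be hidden.

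Among all 23185 genes, 2979 passed limma's test in the tibialis anterior, 1465 higher and 1514 lower in PDX mice, of which 182 and 238 differed at least 1.5-fold, and 1164 and 1298 had the same sign in all 4 cohorts. A tendon mean of Scx, Mkx and the lowered Tnmd, Kera and Chad moved with the treatment partly by construction. Its tumour effect was -1.26, at 4.38 to 6.28 in sham and 3.37 to 4.97 in PDX arrays. As a covariate it multiplied the SE of the tumour effect by 2.28. Limma called 0 genes (1073 at an unadjusted p under 0.05). In that fit the differences were 0.915 for Fkbp5, 1.35 for Serpina3n and 0.179 for Fbxo32. Of the 21 lists that had passed, the glucocorticoid, acute-phase, matrix, basement membrane and oxidative phosphorylation lists kept their call and 16 lost it, among them matrix proteases and glycolysis, which reversed. Medians in that fit were 0.0342 for atrophy (adjusted p = 0.279), -0.0031 for the proteasome (adjusted p = 0.351), 0.0425 for autophagy (adjusted p = 0.845), -0.216 for fibroblasts (adjusted p = 0.0584), -0.0561 for the TCA cycle (adjusted p = 0.351) and -0.0341 for mitochondrial biogenesis (adjusted p = 0.651). The calls of Myh4 and Perm1 were lost in 13 and 10 of the 29 fits that left out 1 array each. Without cohort 1 the calls of Csrp3, Bnip3 and Hbb-b1 were lost, without cohort 3 those of Igf1 and Sln, with the cohort as the replicate those of Csrp3 and Igf1, and those of Perm1 and Myh4 in each of these settings.

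Genes of muscle protein breakdown rose together in the tibialis anterior. Of 34 measured atrophy genes, 21 rose and 3 fell (22 and 4 adjusted over the list alone), with a median log2 difference of 0.419 (camera adjusted p = 1.88e-12, 0.0484 with an estimated correlation). Eif4ebp1, a repressor of translation, rose by 1.38 and Ctsl, a lysosomal protease, by 0.83. Of 26 glucocorticoid-responsive genes, 22 rose and 0 fell (22 and 2 adjusted over the list alone), with a median of 0.775 (adjusted p = 2e-23, 0.0188 with an estimated correlation). Of 31 proteasome subunits, 14 rose and 0 fell (17 and 0 adjusted over the list alone, median 0.185, adjusted p = 6.22e-10), among them Psmd8 (0.52), Psmd4 (0.52) and Psma7 (0.49). This call had adjusted p = 0.166 with an estimated correlation. Of 35 autophagy and lysosome genes, 10 rose and 2 fell (11 and 2 adjusted over the list alone, median 0.113, adjusted p = 0.000165), with Map1lc3b at 0.46 and the mitophagy receptor gene Bnip3 at 0.47. This call had adjusted p = 0.147 with an estimated correlation. Of these 4 lists only the glucocorticoid list kept its call with the tendon covariate.

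Other metabolic stress lists also moved in this muscle. Among 28 genes of oxidative stress and metal response, 9 rose and 3 fell (12 and 3 adjusted over the list alone), with Tfrc, the transferrin receptor, at -1.51. The median was 0.169 (adjusted p = 0.000294). Among 20 genes of amino acid and polyamine metabolism, 4 rose and 0 fell (4 and 0 adjusted over the list alone). The median was 0.061 (adjusted p = 0.0221). Prodh, which starts proline breakdown, rose by 0.92 and Glul, glutamine synthetase, by 0.81. Of 30 cytosolic ribosomal proteins, 5 rose and 0 fell (7 and 0 adjusted over the list alone). The median was 0.062 (adjusted p = 0.00678). The 30 ER stress genes did not pass, with 4 higher and 5 lower (4 and 5 adjusted over the list alone, adjusted p = 0.878), a median of -0.00123, a mean of 0.0236 and a downward test. With an estimated correlation all 3 list calls here were lost (adjusted p from 0.0851 to 0.121).

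Matrix genes fell in the tibialis anterior, as did the tendon genes named above. Of 39 genes of fibrillar collagens and matrix, 0 rose and 34 fell (0 and 34 adjusted over the list alone). The median was -0.855 (camera adjusted p = 1.73e-43, 0.0166 with an estimated correlation). With the tendon gene mean as a covariate the median was -0.148 (adjusted p = 0.00146). Of 19 markers of fibro-adipogenic progenitors and fibroblasts, the connective tissue cells of muscle, 0 rose and 12 fell (0 and 12 adjusted over the list alone), with Mfap5 at -1.37 (0.386-fold), Dpt at -1.35 (0.392-fold) and Lum at -1.21 (0.432-fold). The median was -0.508 (adjusted p = 2.12e-12, 0.0188 with an estimated correlation). Of 18 basement membrane genes, 1 rose and 11 fell (1 and 11 adjusted over the list alone), among them Nid1 (-0.74) and Hspg2 (-0.74). The median was -0.371 (adjusted p = 2.68e-09, 0.0188 with an estimated correlation). Of 26 matrix proteases and inhibitors, 1 rose and 6 fell (1 and 7 adjusted over the list alone), with the gelatinase gene Mmp2 at -0.90. The median was -0.0851 (adjusted p = 0.0117, 0.142 with an estimated correlation). Among 31 genes of TGF-beta, myostatin and activin signalling, 6 were higher and 5 lower (7 and 7 adjusted over the list alone, adjusted p = 0.91), with a median of 0.0422, a mean of 0.00269 and a downward test.

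Genes of mitochondrial energy supply fell in the tibialis anterior, although only oxidative phosphorylation kept its call with the tendon covariate. Of 65 oxidative phosphorylation genes, 0 rose and 37 fell (0 and 51 adjusted over the list alone), with Ndufab1 at -0.58 and Ndufb5 at -0.48, both of complex I. The median was -0.223 (adjusted p = 4e-23). Of 24 TCA cycle genes, 1 rose and 14 fell (1 and 20 adjusted over the list alone), including Dlat (-0.49) and Pdhb (-0.42) of pyruvate dehydrogenase. The median was -0.221 (adjusted p = 6.27e-10). Of 25 genes of mitochondrial biogenesis and dynamics, 1 rose and 8 fell (1 and 11 adjusted over the list alone), with Perm1 at -0.59 and Ckmt2, mitochondrial creatine kinase, at -0.48. The median was -0.155 (adjusted p = 0.00576). Of 24 glycolysis and glycogen genes, 2 rose and 7 fell (3 and 11 adjusted over the list alone). The median was -0.151 (adjusted p = 0.00792). The 29 genes of fatty acid oxidation and uptake did not pass, with 6 higher and 9 lower (8 and 10 adjusted over the list alone, adjusted p = 0.453), a median of -0.0329, a mean of 0.00291 and a downward test. With an estimated correlation all 4 list calls here were lost (adjusted p from 0.121 to 0.386).

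Among contractile and structural lists of the tibialis anterior, only the slow sarcomere list passed. Of 19 slow sarcomere genes, 0 rose and 5 fell (0 and 5 adjusted over the list alone), with Csrp3, a Z-disc protein, at -1.15. The median was -0.118 (adjusted p = 0.0273, 0.353 with an estimated correlation). The 20 fast sarcomere genes did not pass, with 5 higher and 4 lower (6 and 6 adjusted over the list alone, adjusted p = 0.755), a median of 0.00564, a mean of -0.0738 and an upward test. Myh2, the myosin of fast oxidative fibres, had a difference of -1.49 (0.355-fold, adjusted p = 2.84e-06). The 25 denervation and neuromuscular junction genes did not pass (3 higher and 1 lower, also adjusted over the list alone, adjusted p = 0.117), although Sln, an inhibitor of the calcium pump, rose by 1.17 and Chrna1, an acetylcholine receptor subunit, by 0.60. The 26 satellite cell and regeneration genes (2 higher and 6 lower, 3 and 7 adjusted over the list alone, adjusted p = 0.411) and the 19 dystrophin complex genes (3 higher and 6 lower, also adjusted over the list alone, adjusted p = 0.367) did not pass.

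Among inflammation and cell type lists of the tibialis anterior, 12 of 31 STAT3 and acute-phase genes rose and 0 fell (15 and 1 adjusted over the list alone). The median was 0.447 (adjusted p = 1.19e-08). Of 22 neutrophil markers, 6 rose and 0 fell (9 and 0 adjusted over the list alone). The median was 0.217 (adjusted p = 0.000165). In 17 immunoproteasome and antigen presentation genes, 0 rose and 3 fell (0 and 3 adjusted over the list alone). The median was -0.151 (adjusted p = 0.00856). In 24 type I interferon response genes, 1 rose and 3 fell (1 and 5 adjusted over the list alone). The median was -0.108 (adjusted p = 0.0117). Lists that did not pass were NF-kB and cytokine genes (3 higher and 3 lower of 30, 3 and 4 adjusted over the list alone, adjusted p = 0.807), complement (1 and 4 of 18, also adjusted over the list alone, adjusted p = 0.395) and macrophages (1 and 4 of 29, also adjusted over the list alone, adjusted p = 0.257). Lymphocytes (0 and 1 of 22, adjusted p = 0.203), mesothelium (2 and 0 of 17, adjusted p = 0.197) and the cell cycle (0 and 3 of 31, adjusted p = 0.212) did not pass either, with the same counts adjusted over the list alone. Pericytes and smooth muscle (1 and 5 of 16, 2 and 5 adjusted over the list alone, adjusted p = 0.395) and Schwann cells and nerve (0 and 1 of 15, 1 and 2 adjusted over the list alone, adjusted p = 0.533) did not pass. For adipocytes (2 and 3 of 19, 3 and 4 adjusted over the list alone, adjusted p = 0.613) the median was -0.0326, the mean 0.0085 and the test upward. Limma called 0 of the 24 hepatocyte and acinar markers (2 at an unadjusted p under 0.05), also adjusted over the list alone (adjusted p = 0.461). With an estimated correlation all 4 list calls here were lost (adjusted p from 0.138 to 0.353).

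**Figure D1:**
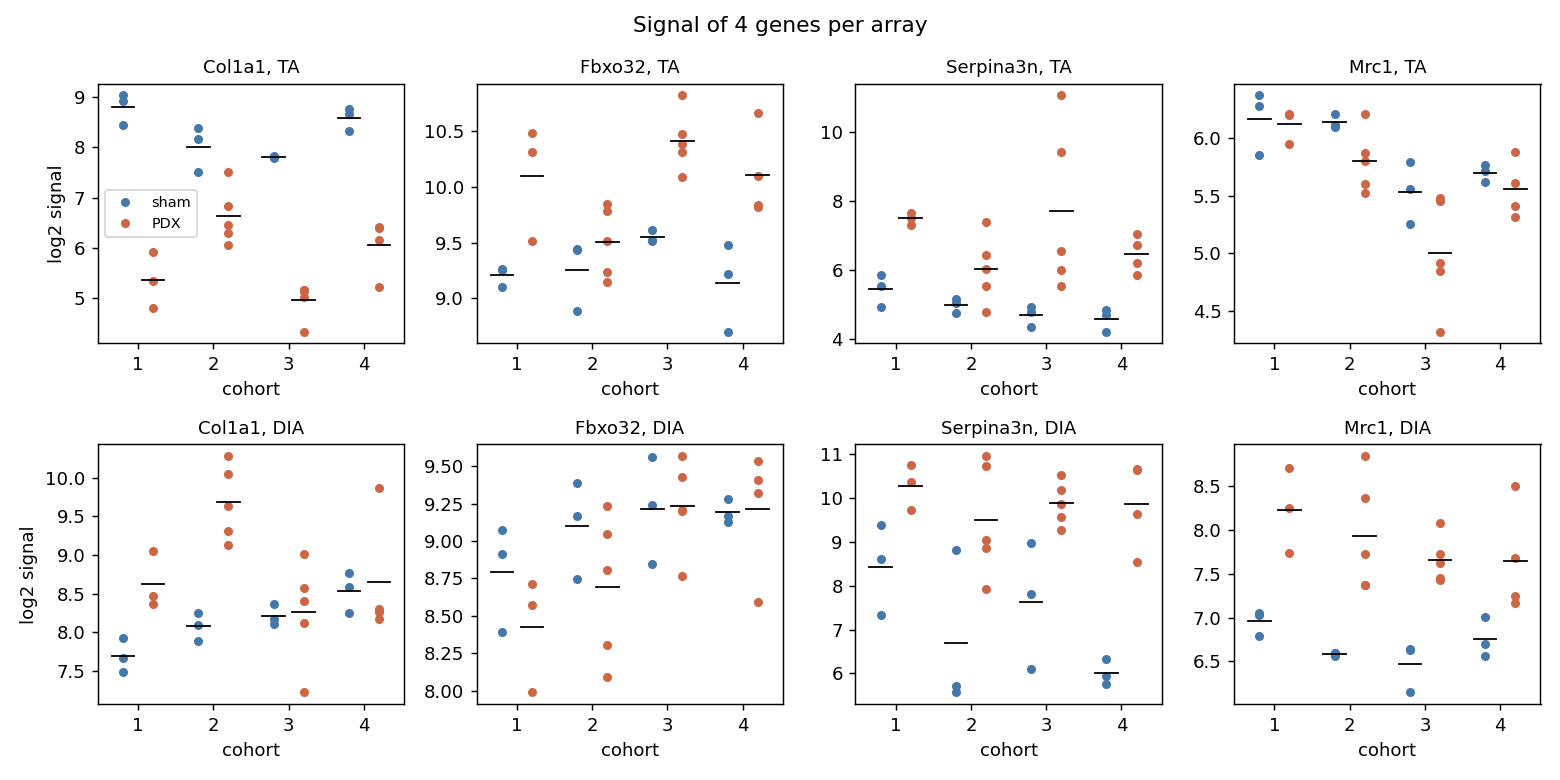
Log2 signal of Col1a1, Fbxo32, Serpina3n and Mrc1 on each array (vertical axes, whose ranges differ between panels) by cohort, in the tibialis anterior and the diaphragm, with sham arrays in blue, PDX arrays in orange and a black line at each group mean. Col1a1 had a mean PDX minus sham log2 difference of -2.55 in the tibialis anterior and 0.68 in the diaphragm.

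In the diaphragm, PDX mice had higher levels of acute-phase, macrophage and matrix genes than sham mice and lower levels of genes of energy metabolism. With a correlation between genes estimated from the data, the matrix list (adjusted p = 0.195) and every list of energy metabolism lost their calls. Serpina3n, the acute-phase protease inhibitor, rose by 2.69 on the log2 scale (6.46-fold, SE 0.38, 17 PDX and 12 sham arrays, adjusted p = 5.18e-05). Saa3, a serum amyloid A protein, rose by 2.39 (5.25-fold, SE 0.40, adjusted p = 0.000269) and Lcn2 by 2.21 (4.63-fold, SE 0.30, adjusted p = 3.87e-05). Mrc1, the mannose receptor of tissue macrophages, rose 2.26-fold (log2 1.18, SE 0.15, adjusted p = 2.33e-05). Tecrl, an endoplasmic reticulum protein of striated muscle, had a log2 difference of -1.84 (0.279-fold, SE 0.22, adjusted p = 7.82e-06).

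Clca3a1 rose by 2.28 in the diaphragm (SE 0.16, adjusted p = 8.31e-09), Chl1, a cell adhesion molecule, by 2.12 (SE 0.43, adjusted p = 0.00145), and the monocyte chemokine gene Ccl8 by 1.93. Mt2 rose by 1.91, Lbp by 1.70, Csf2rb by 1.70, and Apod, apolipoprotein D, by 1.65. Decreases were found for Nmrk2 (-1.52), Abhd18 (-1.44), Cyfip2 (-1.40), Ky (-1.37), Apol6 (-1.29), Slc41a3 (-1.27), and Grb14 (-1.19, SE 0.11, adjusted p = 4.15e-07). Aqp4, a water channel of fast fibres, and Mcpt4, a mast cell protease, each had a difference of -1.16. These genes had the same sign in the 4 cohorts. Cebpd rose by 0.70 (adjusted p = 0.000951), Foxo1 by 0.24 (adjusted p = 0.0139), Col1a1 by 0.68 (SE 0.18, adjusted p = 0.0127) and Col3a1 by 0.66 (SE 0.18, adjusted p = 0.0152), with cohort values for Col1a1 of 0.93, 1.61, 0.05 and 0.11 and for Col3a1 of 0.93, 1.65, -0.053 and 0.11. Genes that did not pass were Fbxo32 (-0.18, adjusted p = 0.474), Trim63 (0.079, adjusted p = 0.859), Mstn (-0.44, adjusted p = 0.208), Ppargc1a (-0.18, adjusted p = 0.673), Igf1 (0.11, adjusted p = 0.881), Myh4 (-1.12, adjusted p = 0.0905) and Myh7 (-0.14, adjusted p = 0.615).

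Of the 23185 genes, 2892 passed limma's test in the diaphragm, 1366 higher and 1526 lower in PDX mice, of which 313 and 172 differed at least 1.5-fold, and 1074 and 1311 had the same sign in all 4 cohorts. Hepatocyte transcripts were present in part of the diaphragm arrays of both treatments: the mean of the 24 hepatocyte and acinar markers lay between 5.18 and 7.30 on 15 arrays (9 of 17 PDX and 6 of 12 sham) and between 3.58 and 4.07 on 14. In the tibialis anterior it lay between 3.15 and 4.89, with the highest values on 2 PDX arrays of cohort 4 (4.89 and 4.52) and a sham array of cohort 3 (4.44). Limma called 0 of the 24 markers between PDX and sham (0 at an unadjusted p under 0.05), also adjusted over the list alone (median -0.0668, adjusted p = 0.992). With that mean as a covariate 3463 genes passed, 2889 of them shared with the 2892, and over cohorts 2 to 4 without the 15 arrays 654 passed, 560 of them shared. In the latter setting Serpina3n, Clca3a1, Lcn2, Ccl8, Csf2rb, Tecrl and Cd68 still passed, while Saa3 (2.59, adjusted p = 0.0585), Chl1 (2.27, adjusted p = 0.117), Mrc1 (1.11, adjusted p = 0.0567), Ky (-1.18), Aqp4 (-0.837), Cebpd (0.46), Foxo1 (0.362), Col1a1 (0.874) and Col3a1 (0.729) did not. Nor did Timp1 (1.62), Lox (1.13), Ctss (1.12), Postn (1.05), Vcam1 (0.949), Msln (0.844), Mki67 (0.542), Top2a (0.502), Perm1 (-0.802), Esrrb (-0.618), Plin5 (-0.583), Ndufc1 (-0.469), Acads (-0.467), Pdhb (-0.426) or Dlat (-0.386), in fits of fewer arrays. The calls of Col1a1, Col3a1, Top2a and Mki67 were also lost without cohort 1, without cohort 2 and with the cohort as the replicate, and that of Top2a without cohort 3. With the cohort as the replicate Cebpd, Foxo1, Postn and Plin5 lost theirs too, as did Foxo1 without cohort 3, Postn without cohort 2 and Plin5 without cohort 1.

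**Figure D2:**
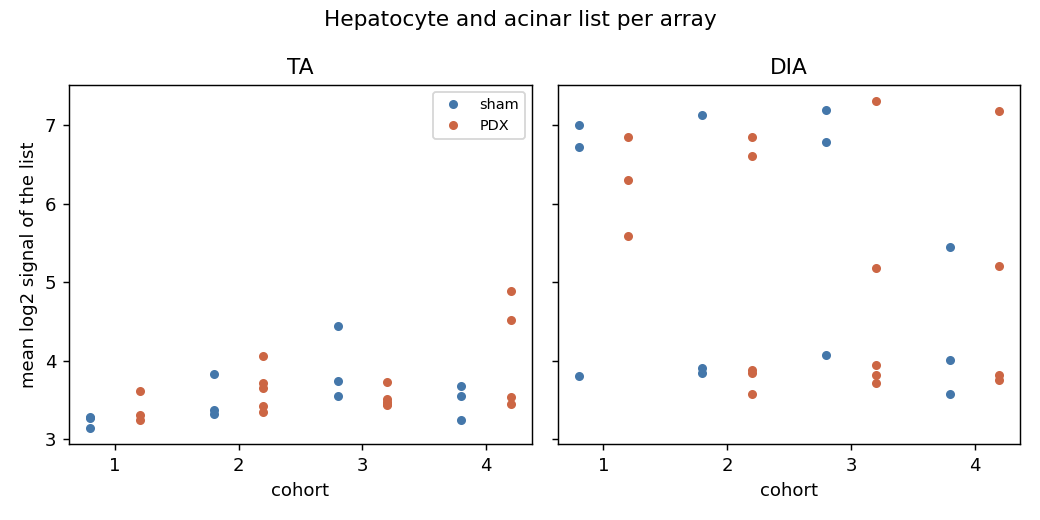
Mean log2 signal of the 24 hepatocyte and pancreatic acinar markers on each array (vertical axis) by cohort in the tibialis anterior and the diaphragm, with sham arrays in blue and PDX arrays in orange. On 15 of the 29 diaphragm arrays the mean lies above 5.

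Macrophage and complement genes rose together in the diaphragm. Of 29 macrophage and monocyte markers, 23 rose and 0 fell (25 and 0 adjusted over the list alone), with Ms4a7 at 1.60 (3.03-fold) and the lysosomal protein gene Cd68 at 1.32 (2.50-fold). The median was 0.768 (camera adjusted p = 1.01e-26, 0.0424 with an estimated correlation). The median over cohorts 2 to 4 without the arrays with hepatocyte transcripts was 0.721. Of 18 complement genes, 10 rose and 0 fell (13 and 0 adjusted over the list alone), with C7 at 1.48 and C1qc at 0.97. The median was 0.729 (adjusted p = 1.94e-11, 0.0424 with an estimated correlation). Of 31 STAT3 and acute-phase genes, 15 rose and 0 fell (17 and 0 adjusted over the list alone). The median was 0.564 (adjusted p = 4.32e-15, 0.0424 with an estimated correlation). Of 17 immunoproteasome and antigen presentation genes, 7 rose and 0 fell (10 and 0 adjusted over the list alone), with H2-Aa at 1.37 and Cd74 at 1.27, both of the class II pathway. The median was 0.298 (adjusted p = 2.16e-07, 0.101 with an estimated correlation). Of 30 NF-kB and cytokine genes, 11 rose and 1 fell (13 and 1 adjusted over the list alone), including Vcam1, an adhesion molecule for leukocytes (1.05). The median was 0.20 (adjusted p = 1.08e-07, 0.125 with an estimated correlation). Of 22 neutrophil markers, 2 rose and 0 fell (1 and 0 adjusted over the list alone). The median was 0.162 (adjusted p = 0.000798, 0.196 with an estimated correlation). Interferon response genes (2 higher and 1 lower of 24, adjusted p = 0.318) and lymphocyte markers (1 and 1 of 22, adjusted p = 0.772) did not pass, with the same counts adjusted over the list alone.

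Matrix genes rose in the diaphragm. Of 39 genes of fibrillar collagens and matrix, 19 rose and 2 fell (28 and 3 adjusted over the list alone), with Lox, which crosslinks collagen, at 1.05, Postn at 0.94 and Thbs2 at 0.87. The median was 0.397 (adjusted p = 3.73e-11). Of 26 matrix proteases and inhibitors, 15 rose and 1 fell (16 and 1 adjusted over the list alone), with Timp1 at 1.47 and the cathepsin gene Ctss at 1.06. The median was 0.456 (adjusted p = 1.19e-09). Of 31 TGF-beta, myostatin and activin genes, 8 rose and 0 fell (10 and 0 adjusted over the list alone). The median was 0.122 (adjusted p = 0.002). Of 19 fibro-adipogenic and fibroblast markers, 4 rose and 1 fell (4 and 1 adjusted over the list alone). The median was 0.156 (adjusted p = 0.0027). Of 17 mesothelial markers, the lining of the body cavities, 5 rose and 0 fell (6 and 0 adjusted over the list alone), with Msln at 0.90. The median was 0.285 (adjusted p = 2.03e-05). Of 31 cell cycle genes, 6 rose and 0 fell (16 and 1 adjusted over the list alone), with the proliferation genes Top2a and Mki67 at 0.48 each. The median was 0.199 (adjusted p = 4.8e-06). The 18 basement membrane genes did not pass (0 higher and 1 lower, also adjusted over the list alone, adjusted p = 0.846), nor did 16 pericyte and smooth muscle markers (3 and 3, 4 and 3 adjusted over the list alone, adjusted p = 0.495). With an estimated correlation all 6 list calls here were lost (adjusted p from 0.101 to 0.35).

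Genes of energy metabolism fell in the diaphragm. Of 65 oxidative phosphorylation genes, 0 rose and 38 fell (0 and 55 adjusted over the list alone), with Ndufab1 at -0.54 and Ndufc1 at -0.49. The median was -0.298 (adjusted p = 4.8e-25). Of 24 TCA cycle genes, 0 rose and 14 fell (0 and 21 adjusted over the list alone), with Dlat at -0.44 and Pdhb at -0.41. The median was -0.273 (adjusted p = 2.69e-12). Of 29 fatty acid oxidation and uptake genes, 0 rose and 13 fell (0 and 15 adjusted over the list alone), with the lipid droplet gene Plin5 at -0.55 and Acads at -0.41. The median was -0.26 (adjusted p = 3.23e-07). Of 25 mitochondrial biogenesis and dynamics genes, 0 rose and 11 fell (0 and 15 adjusted over the list alone), with Perm1 at -0.84 and Esrrb at -0.63. The median was -0.239 (adjusted p = 1.11e-09). Of 24 glycolysis and glycogen genes, 2 rose and 11 fell (2 and 17 adjusted over the list alone), with Phkg1, a subunit of phosphorylase kinase, at -0.97. The median was -0.287 (adjusted p = 5.33e-06). Of 19 slow sarcomere genes, 1 rose and 2 fell (1 and 7 adjusted over the list alone). The median was -0.204 (adjusted p = 0.00875). Of 20 fast sarcomere genes, 0 rose and 2 fell (0 and 2 adjusted over the list alone). The median was -0.0706 (adjusted p = 0.0185). Of 19 adipocyte markers, 0 rose and 2 fell (0 and 2 adjusted over the list alone, median -0.123, adjusted p = 0.0465). Without the arrays with hepatocyte transcripts the slow (adjusted p = 0.062) and fast (adjusted p = 0.617) sarcomere lists lost their calls. With an estimated correlation all 8 list calls here were lost (adjusted p from 0.145 to 0.624).

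Glucocorticoid-responsive genes rose in the diaphragm too, 14 of 26, with 1 lower (15 and 1 adjusted over the list alone, median 0.335, adjusted p = 5.19e-09, 0.08 with an estimated correlation), and Fkbp5 rose by 1.53 (2.88-fold, SE 0.21). The 34 atrophy genes did not pass there, with 8 higher and 5 lower (8 and 6 adjusted over the list alone, adjusted p = 0.928), a median of -0.0471, a mean of 0.0657 and an upward test. Eif4ebp1 rose by 0.87 and Asb2, a ubiquitin ligase subunit, had a difference of -1.08. Autophagy and lysosome genes (3 higher and 2 lower of 35, adjusted p = 0.887), proteasome subunits (0 and 1 of 31, adjusted p = 0.262), ribosomal proteins (4 and 0 of 30, adjusted p = 0.0743) and ER stress genes (3 and 0 of 30, adjusted p = 0.892) did not pass, with the same counts adjusted over the list alone. Amino acid metabolism (4 and 4 of 20, 4 and 5 adjusted over the list alone, adjusted p = 0.846), oxidative stress and metal response (6 and 2 of 28, 7 and 2 adjusted over the list alone, adjusted p = 0.0606) and satellite cell genes (4 and 4 of 26, 5 and 5 adjusted over the list alone, adjusted p = 0.197) did not pass. For denervation genes (2 and 4 of 25, 4 and 4 adjusted over the list alone, adjusted p = 0.892) the median was -0.0337, the mean 0.0279 and the test downward. For the dystrophin complex (2 and 2 of 19, also adjusted over the list alone, adjusted p = 0.893) the median was 0.0431, the mean -0.0406 and the test upward. Schwann and nerve markers (1 and 3 of 15, also adjusted over the list alone, adjusted p = 0.673) did not pass.

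**Figure D3:**
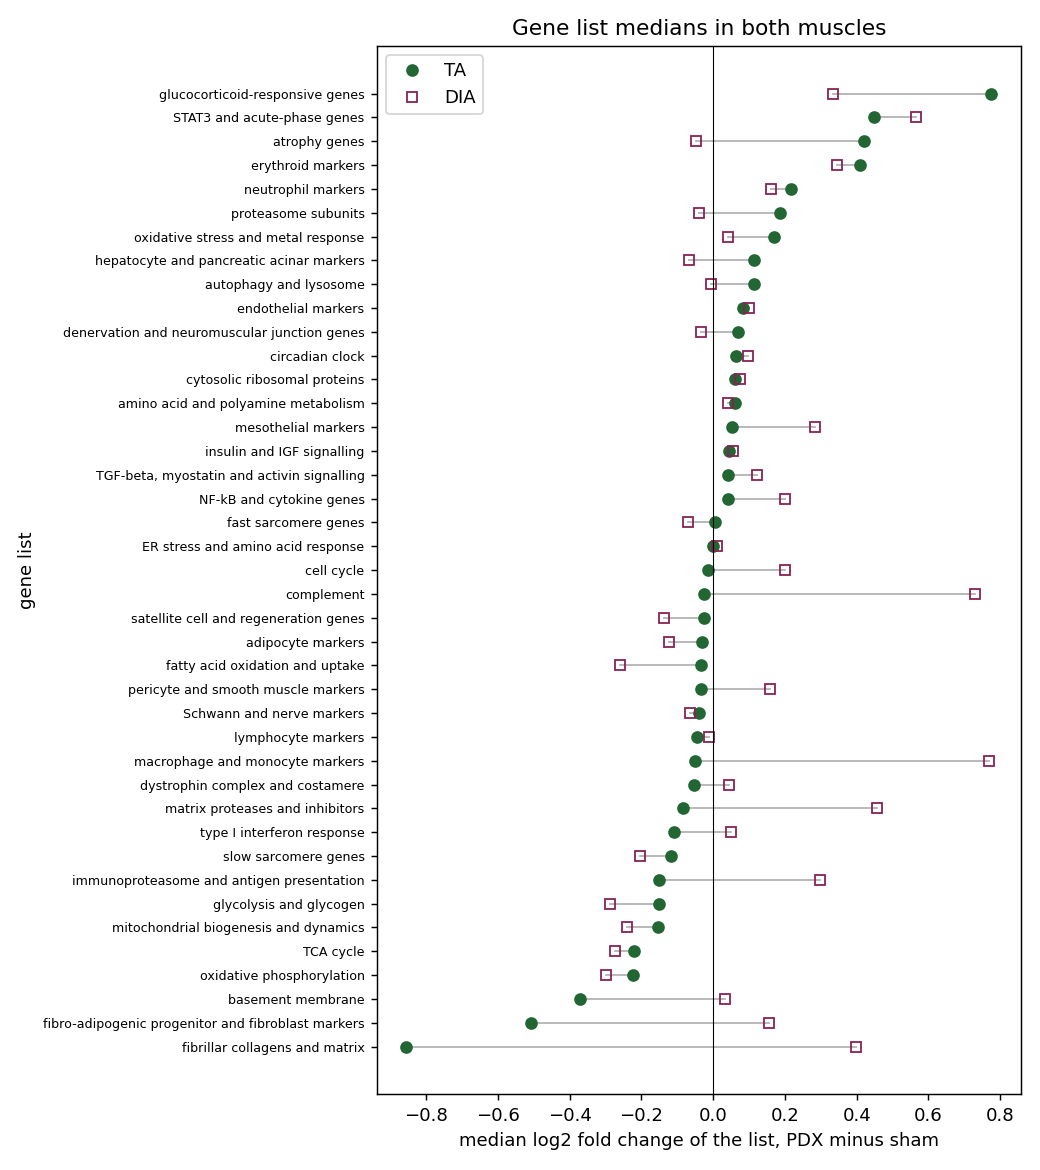
Median PDX minus sham log2 difference of each of the 41 gene lists (horizontal axis), with filled circles for the tibialis anterior and open squares for the diaphragm. The list of fibrillar collagens and matrix has medians of -0.855 and 0.397, and the macrophage and monocyte list of -0.0499 and 0.768.

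The series title sets limb muscle against respiratory muscle, a difference that the diaphragm effect minus the tibialis anterior effect tests directly. Col1a1 differed by 3.23 on the log2 scale (SE 0.25, 58 arrays, adjusted p = 7.08e-13), Col1a2 by 2.70 (SE 0.22, adjusted p = 8.59e-12) and Col3a1 by 2.54 (SE 0.24, adjusted p = 2.33e-10). Fbxo32 and Trim63 differed by -0.93 (SE 0.18, adjusted p = 0.000557) and -0.84 (adjusted p = 0.0213), and only their effects in the tibialis anterior passed. Mrc1 differed by 1.44 (SE 0.19, adjusted p = 9.03e-07) and Cd74 by 1.62 (SE 0.21, adjusted p = 6.34e-07).

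Sfrp4, a secreted Wnt antagonist, had a log2 difference of -1.19 in the tibialis anterior and 1.19 in the diaphragm, Postn of -1.18 and 0.94, and Thbs4 of -1.24 and 0.71, so that their effects differed by 2.37, 2.12 and 1.95. Ighm differed by 2.01 and Chl1 by 1.95. On the other side, Tecrl differed by -1.77, Depp1 by -1.44, Lrrc30 by -1.32, Rpl6, a ribosomal protein, by -1.31, Gadd45g by -1.29 (adjusted p = 0.0127) and Odf3l2 by -1.20. A1bg (-1.44, adjusted p = 0.048) lost its call in 45 of the 58 fits that left out 1 array each, and Inmt (-1.34, adjusted p = 0.0333) in 6. In total 1468 genes passed, 849 with a higher and 619 with a lower diaphragm effect, of which 421 and 125 differed at least 1.5-fold, and 748 and 511 had the same sign in all 4 cohorts. Over cohorts 2 to 4 without the diaphragm arrays with hepatocyte transcripts, 515 passed, 437 of them shared, and the calls of Chl1 (2.06), Inmt (-1.32), Depp1 (-1.31), Gadd45g (-1.22), Igfbp3 (-1.03), Pdk4 (-1), Odf3l2 (-0.869), Klf15 (-0.67) and A1bg (-0.381) were lost. Without cohort 1, 531 genes passed, not among them Chl1, Gadd45g, Inmt, Pdk4, Psmc6 and A1bg, and without cohort 2, 705, without Inmt and A1bg.

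Of the 41 lists, 22 passed in the difference between the muscles. Matrix genes had the higher diaphragm effect in 33 of 39 and the lower in 0 (38 and 0 adjusted over the list alone, median 1.13, camera adjusted p = 1.12e-67, 0.000252 with an estimated correlation), beside tendon genes such as Tnmd, whose effects differed by 1.46. Macrophage markers did so in 19 of 29 with 0 lower (25 and 0 adjusted over the list alone), with Ms4a7 at 1.64 and C1qb at 1.30. The median was 0.854 (adjusted p = 1.98e-31, 0.00148 with an estimated correlation). For fibro-adipogenic and fibroblast markers it was 11 of 19 and 0 (12 and 0 adjusted over the list alone), with Pi16 at 1.63 and Lum at 1.61. The median was 0.574 (adjusted p = 9.69e-19, 0.00159 with an estimated correlation). Matrix proteases and inhibitors had 12 of 26 and 0 (13 and 0 adjusted over the list alone), with Timp1 at 1.69 and Mmp2 at 1.53. The median was 0.42 (adjusted p = 1.12e-12, 0.00387 with an estimated correlation). Complement had 8 of 18 and 0 (9 and 0 adjusted over the list alone). The median was 0.638 (adjusted p = 1.01e-12, 0.00233 with an estimated correlation). Immunoproteasome and antigen presentation genes had 6 of 17 and 0 (14 and 0 adjusted over the list alone). The median was 0.405 (adjusted p = 2.4e-12, 0.00233 with an estimated correlation). Basement membrane genes had 6 of 18 and 0 (8 and 0 adjusted over the list alone). The median was 0.26 (adjusted p = 4.56e-09, 0.0123 with an estimated correlation). Cell cycle genes had 6 of 31 and 0 (11 and 0 adjusted over the list alone, median 0.212, adjusted p = 2.31e-07, 0.0356 with an estimated correlation).

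The effect on atrophy genes was lower in the diaphragm for 13 of 34 and higher for 0 (17 and 0 adjusted over the list alone), with Sesn1 at -1.15, Pdk4 at -1.10 and Klf15 at -0.79. The median was -0.492 (adjusted p = 1.47e-13, 0.0123 with an estimated correlation). Proteasome subunits had 10 of 31 lower and 0 higher (15 and 0 adjusted over the list alone), with Psma4 at -0.49 and Psmc6 at -0.48. The median was -0.223 (adjusted p = 6.57e-12, 0.105 with an estimated correlation). Glucocorticoid-responsive genes had 6 of 26 lower and 0 higher (10 and 0 adjusted over the list alone). The median was -0.381 (adjusted p = 3.56e-07, 0.116 with an estimated correlation). Autophagy and lysosome genes had 5 of 35 lower and 1 higher (11 and 2 adjusted over the list alone). The median was -0.0942 (adjusted p = 0.000414, 0.116 with an estimated correlation). Amino acid metabolism had 4 of 20 lower and 0 higher (7 and 0 adjusted over the list alone). The median was -0.144 (adjusted p = 0.0147, 0.105 with an estimated correlation). Fatty acid oxidation and uptake had 4 of 29 lower and 0 higher (6 and 0 adjusted over the list alone, median -0.193, adjusted p = 0.000101, 0.208 with an estimated correlation).

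Lower diaphragm effects also passed for mitochondrial biogenesis (2 of 25, also adjusted over the list alone, median -0.134, adjusted p = 0.00335). Adipocyte markers had 1 of 19 lower (also adjusted over the list alone). The median was -0.359 (adjusted p = 0.00161). Glycolysis and glycogen had 2 of 24 lower and 1 higher (3 and 1 adjusted over the list alone). The median was -0.185 (adjusted p = 0.0176). Higher effects passed for NF-kB and cytokine genes (6 of 30, 10 adjusted over the list alone, median 0.238, adjusted p = 3.04e-05). Interferon response genes had 2 of 24 higher (also adjusted over the list alone). The median was 0.133 (adjusted p = 0.00828). TGF-beta genes had 5 of 31 higher and 0 lower (10 and 3 adjusted over the list alone). The median was 0.164 (adjusted p = 0.00792). Mesothelial markers had 2 of 17 higher (also adjusted over the list alone). The median was 0.28 (adjusted p = 0.00161). Pericyte and smooth muscle markers had 1 of 16 higher (1 and 1 lower adjusted over the list alone). The median was 0.169 (adjusted p = 0.0252). The remaining 19 lists did not pass, with adjusted p from 0.0586 for STAT3 and acute-phase genes to 0.95 for slow sarcomere genes, and limma called 0 of the 65 oxidative phosphorylation genes (3 at an unadjusted p under 0.05), also adjusted over the list alone (median -0.0665, adjusted p = 0.1), although this list passed without the arrays with hepatocyte transcripts (adjusted p = 5.99e-05), with the array upper quartile as a covariate (adjusted p = 0.0336) and without cohort 1 or 3. Acute-phase genes passed with the hepatocyte covariate (adjusted p = 0.0365), the upper quartile (adjusted p = 0.043) and without cohort 3, endothelial markers without the hepatocyte arrays (adjusted p = 0.0495) and without cohort 4, and 4 further lists without 1 of the cohorts. Median and test differed in sign for hepatocyte markers (median -0.195, test upward), Schwann and nerve markers (median -0.0273, test upward) and slow sarcomere genes (median -0.0611, test upward), and for insulin and IGF signalling the mean (0.021) differed in sign from the median (-0.0972) and the test (downward). With an estimated correlation all 8 list calls here were lost (adjusted p from 0.183 to 0.601).

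Part of the response was shared between the muscles. In both, 285 genes were higher and 548 lower in PDX mice, against 86.3 and 99.7 for independent lists, while 106 were lower in the tibialis anterior and higher in the diaphragm (89.2 for independent lists) and 18 were the reverse (96.4). Lcn2, Mt2, Serpina3n, Fkbp5 and Eif4ebp1 were among genes higher in both muscles, and Cyfip2, Ndufab1 and Perm1 among those lower in both. Across genes, which are not independent replicates, the log2 differences of the muscles had a Pearson correlation of 0.314 and a Spearman correlation of 0.226. The 100 permutations had a median of 0.0487 and a highest value of 0.259 for Pearson's correlation, and 0.0507 and 0.228 for Spearman's, so that the highest permuted value lay above the observed one. The covariance was 0.0137, against a permuted median of 0.000631.

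The cohorts, which differed in the tumour they carried, gave different numbers of calls. In the tibialis anterior, cohort 1 had 570 genes past the threshold (267 higher, 303 lower), cohort 3 had 1845 (901 and 944) and cohort 4 had 70 (21 and 49), while limma called 0 in cohort 2 (1265 at an unadjusted p under 0.05). In the diaphragm the counts were 8 (5 and 3), 624 (512 of them higher), 246 (140 and 106) and 89 (15 and 74) for cohorts 1 to 4. The order of the cohorts is not firm: group sizes differed, leaving out 1 array moved the count from 211 to 932 in tibialis anterior cohort 1 and from 0 to 114 and 4 to 231 in diaphragm cohorts 1 and 4, and array weights gave 2648 and 1035 in tibialis anterior cohorts 1 and 3 and 1158 in diaphragm cohort 1. Limma's F test found 3 genes whose effect differed between cohorts in the tibialis anterior: Slc25a25, a mitochondrial carrier, with cohort values of -0.20, 0.63, 1.69 and -0.13 (adjusted p = 0.0451), the immunoglobulin segment gene Igkv5-43 with -0.51, -0.23, 0.89 and -0.023 (adjusted p = 0.0451), at mean levels of only 1.24 in sham and 1.28 in PDX arrays, and Mir1192, chosen outside the rule for named genes after its values were seen. The count moved in 24 of the 29 fits that left out 1 array, to 0 by limma in 19 of them (1454 to 2060 unadjusted), and was 0 with the array upper quartile as a covariate (2005 unadjusted). Errfi1, Per1 and Mfsd4b1 did not pass there (adjusted p = 0.12 each). In the diaphragm the only gene to pass was Per1, a component of the circadian clock, with cohort values of 0.44, 0.13, 2.43 and 0.048 (adjusted p = 0.000652). Zfp558, Spats2l, Rybp and Nr4a1 did not pass (adjusted p from 0.0765 to 0.108). Correlations of the log2 differences between cohorts, across genes, ran from 0.332 (cohorts 2 and 3) to 0.54 (cohorts 1 and 3) in the tibialis anterior and from 0.00681 (cohorts 3 and 4) to 0.62 (cohorts 1 and 2) in the diaphragm.

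The sham muscles differed first in their fibre types, which serves as a check of the muscle labels. Slow-fibre genes were higher in the sham diaphragm: Sln by 6.23 on the log2 scale (75.1-fold, SE 0.23, 12 arrays per muscle), Myl2 by 5.76 (54.0-fold, SE 0.18), the slow myosin Myh7 by 5.69 (51.5-fold, SE 0.15), Tnnt1 by 4.91 (30.1-fold) and Tnni1 by 4.20 (18.4-fold). Pkhd1l1 (4.62) and Tecrl (4.44) were also higher, and so was Cyp2e1 (4.62, 24.6-fold), a cytochrome P450 of hepatocytes and a member of the hepatocyte list. Genes lower in the diaphragm were Mss51 (-4.09, 0.0588-fold), the limb homeobox gene Hoxc10 (-3.88), Tbc1d1 (-3.58), the lactate transporter gene Slc16a3 (-3.44), Mettl11b (-3.21), Ostn (-2.98), Atp1b2 (-2.69) and Sim1 (-2.56). In total 9210 genes passed, 3520 higher and 5690 lower in the diaphragm, of which 1523 and 629 differed at least 1.5-fold, and 3122 and 4258 had the same sign in all 4 cohorts. Over cohorts 2 to 4 without the diaphragm arrays with hepatocyte transcripts, 4366 genes passed, 2195 higher and 2171 lower, and the call of Alb (4.00 with all arrays, adjusted p = 0.00031) was lost.

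Of the 41 lists, 25 passed between the sham muscles, 21 higher and 4 lower in the diaphragm. Slow sarcomere genes were higher in 15 of 19 (15 adjusted over the list alone, median 2.42, adjusted p = 7.7e-29, 0.000977 with an estimated correlation). Mesothelial markers were higher in 15 of 17 (15 adjusted over the list alone), among them Gpm6a (4.15) and Upk3b (3.77). The median was 1.92 (adjusted p = 3.37e-26, 4.09e-05 with an estimated correlation). Fatty acid oxidation and uptake had 27 of 29 higher and 1 lower (27 and 1 adjusted over the list alone), with the lipid-sensing receptor gene Ppara at 1.73. The median was 0.716 (adjusted p = 1.63e-23, 0.000977 with an estimated correlation). Macrophage markers had 23 of 29 higher (24 adjusted over the list alone), with Itgam at 2.82. The median was 0.751 (adjusted p = 4.55e-15, 0.0232 with an estimated correlation). Complement had 15 of 18 higher and 1 lower (16 and 1 adjusted over the list alone), with C4b at 3.10. The median was 1.09 (adjusted p = 1.96e-13, 0.00213 with an estimated correlation). Interferon response genes had 20 of 24 higher (20 adjusted over the list alone), with Oasl2 at 1.62. The median was 0.681 (adjusted p = 1.13e-13, 0.00874 with an estimated correlation). Adipocyte markers had 15 of 19 higher and 1 lower (16 and 2 adjusted over the list alone), with Scd1 at 3.40. The median was 0.726 (adjusted p = 1.98e-12, 0.0189 with an estimated correlation). Immunoproteasome and antigen presentation genes had 12 of 17 higher and 2 lower (13 and 2 adjusted over the list alone). The median was 0.507 (adjusted p = 3.1e-08, 0.0188 with an estimated correlation). Lists lower in the diaphragm were fast sarcomere genes (15 of 20, with Mylk2 at -2.05, adjusted p = 2.75e-07, 0.216 with an estimated correlation), glycolysis and glycogen (16 of 24, adjusted p = 3.1e-08, 0.12 with an estimated correlation), proteasome subunits (23 of 31, adjusted p = 3.1e-08, 0.216 with an estimated correlation) and lymphocyte markers (8 of 22, adjusted p = 0.0288, 0.272 with an estimated correlation). Adjusted over the list alone, those counts were 15, 18, 26 and 7.

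The other 13 lists higher in the sham diaphragm lost their call with an estimated correlation. Hepatocyte and acinar markers were higher for 13 of 24 and lower for 4 (13 and 6 adjusted over the list alone). The median was 2.67 (adjusted p = 0.00944, 0.364 with an estimated correlation). The other 12 were oxidative stress and metal response, insulin and IGF signalling, fibroblasts, ER stress, matrix, acute-phase, NF-kB, basement membrane, matrix protease and denervation genes, endothelial markers and the TCA cycle (adjusted p from 0.0538 to 0.655 with an estimated correlation). For matrix proteases the median (-0.00289) and the test (upward) differed in sign. The remaining 16 lists did not pass, with adjusted p from 0.0626 for glucocorticoid-responsive genes to 0.735 for pericyte and smooth muscle markers. Among these, median and test differed in sign for autophagy, TGF-beta, neutrophil, Schwann, mitochondrial biogenesis and cell cycle genes.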

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

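The tests on tendon transcripts and immediate-early genes were chosen only after their results were seen; the settings for liver RNA and the signal distribution were added after the data were seen, but their bounds, like those for the clock, before the values tested.

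The effect of the tumour differed between the muscles by limma's test for 53 of the genes named for either muscle (diaphragm effect minus tibialis anterior effect, log2). Matrix and tendon genes had Col1a1 3.23, Col1a2 2.70, Col3a1 2.54, Postn 2.12, Timp1 1.69, Lum 1.61, Mmp2 1.53, Mfap5 1.53, Kera 1.5, Tnmd 1.46, Fmod 1.45, Dpt 1.362, Thbs2 1.10, Hspg2 0.799 and Nid1 0.76. Immune genes had Ighm 2.01, Ccl8 1.76, Ms4a7 1.64, Cd74 1.62, Lbp 1.57, H2-Aa 1.57, Mrc1 1.44, Cd68 1.41, C7 1.37, C1qc 1.29, Ctss 1.11 and Vcam1 1.06. Other genes with a higher effect in the diaphragm were Chl1 1.95, Myh2 1.41, Apod 1.21, Ostn 1.13, Igfbp5 1.12, Clca3a1 1.10, Msln 0.93, Top2a 0.641 and Mki67 0.486. Lower effects in the diaphragm were found for Tecrl -1.77, Depp1 -1.44, Igfbp3 -1.15, Il6ra -1.11, Sln -1.01, Abhd18 -0.957, Cebpd -0.935, Apol6 -0.932, Fbxo32 -0.929, Trim63 -0.836, Asb2 -0.823, Cep85l -0.763, Bnip3 -0.719, Phkg1 -0.621, Foxo1 -0.552, Glul -0.457 and Psmd8 -0.368.

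The same difference passed for 22 lists, 9 of which held with an estimated correlation, with medians of 1.13 for matrix, 0.854 for macrophages, 0.638 for complement, 0.574 for fibroblasts, 0.42 for matrix proteases, 0.405 for the immunoproteasome, 0.28 for mesothelium, 0.26 for basement membrane, 0.238 for NF-kB, 0.212 for the cell cycle, 0.169 for pericytes, 0.164 for TGF-beta and 0.133 for interferon. Medians were -0.492 for atrophy, -0.381 for glucocorticoid response, -0.359 for adipocytes, -0.223 for the proteasome, -0.193 for fatty acid oxidation, -0.185 for glycolysis, -0.144 for amino acids, -0.134 for mitochondrial biogenesis and -0.0942 for autophagy. Effects differed between cohorts for Slc25a25 and Igkv5-43 in the tibialis anterior (adjusted p = 0.0451 each, a count that moved in 24 of 29 fits without 1 array) and Per1 in the diaphragm (adjusted p = 0.000652).

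Single arrays stood apart in 19 of 387 groups of values tested, where chance gives about 1 in 20, and the gap to the nearest array as a share of the group's range follows each. In PDX tibialis anterior of cohort 2, replicate 1 was highest for Psmd4 (0.8063), Psma7 (0.7768) and Sln (0.7348) and lowest for Ndufb5 (0.7344) and Ckmt2 (0.7219), replicate 3 was highest for Chad (0.8251), and replicate 5 was highest for Foxo1 (0.821). In cohort 3, replicate 5 was lowest for Ighm (0.7884) and Psmd4 (0.8291), replicate 1 lowest for Col1a1 (0.8208) and replicate 4 highest for Chrna1 (0.8224), and in cohort 4 replicate 3 was lowest for Igf1 (0.8644). In PDX diaphragm, Timp1 was highest in replicate 5 of cohort 2 (0.7307) and replicate 2 of cohort 3 (0.7477), replicate 4 of cohort 3 was lowest for Apod (0.7834), Cebpd (0.7504) and Pdhb (0.7315), and replicate 2 of cohort 4 was highest for Col1a1 (0.9253) and Col3a1 (0.9429). Of the 2021 probe sets without a symbol, which no comparison used, 201 passed in the tibialis anterior and 175 in the diaphragm.

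The first pattern is the lower level of matrix genes in the PDX tibialis anterior. The matrix median was -0.852 with the array upper quartile as a covariate (-0.855 without). After quantile normalization this cannot test the signal distribution as a cause. Less tendon in the dissected PDX muscle may be part of the pattern: with the mean of 5 tendon genes as a covariate the matrix median moved to -0.148 (-0.282 to -0.122 with each array left out) and the basement membrane median from -0.371 to -0.191, with both lists still past the threshold (adjusted p = 0.00146 and 0.0489). By the rule written for that test the tendon explanation would have held for the matrix list, but a control added after that result was seen showed that the covariate also took the atrophy median from 0.419 to 0.0342, though the glucocorticoid median (0.775 to 0.459) still passed (adjusted p = 1.2e-08), and 0.85 of the variance of the tendon mean lay between the groups, so for both lists tendon and a lower expression in the muscle itself cannot be told apart. A biological change in muscle matrix stays open too and was not tested apart from this.

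The second pattern is the rise of macrophage, acute-phase and matrix lists in the PDX diaphragm beside hepatocyte transcripts on 15 of 29 arrays, where Alb lay between 9.99 and 12.4 against 5.27 to 8.05 on the others. Of the 24 hepatocyte and acinar markers, 11 lay above the median of all probe sets in sham tibialis anterior, and 1, Fgb, is in another list. Liver RNA as the cause is argued against by the medians over cohorts 2 to 4 without those arrays: 0.721 for macrophages (0.746 with them), 0.485 for acute-phase genes (0.564) and 0.506 for matrix (0.353). Cohort 1 could not be tested this way, because all 3 of its PDX diaphragm arrays held these transcripts. A response of the muscle to the tumour stays open as a hypothesis.

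The third pattern is Per1, whose tumour effect in cohort 3 exceeded that of the other cohorts by 1.32 in the tibialis anterior and 2.23 in the diaphragm. A different time of day of tissue collection may contribute: 5 of 18 clock genes in the tibialis anterior and 8 of 18 in the diaphragm also differed in cohort 3. An immediate-early response at collection went with the tibialis anterior, where 6 of 10 such genes differed. In the diaphragm these 10 argue against it (limma called 0, 0 unadjusted). Outside them, Nr4a1 had 1.77 there in cohort 3 and -0.91 to -0.33 in others. The labels give no collection times, and the cohorts' tumours differed too, an open and untested explanation.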

How the results depend on the processing

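The settings with hepatocyte transcripts, the array upper quartile, tendon transcripts or 3 tibialis anterior arrays left out were chosen only after the data were seen. Outside the fits that left out 1 array, 2316 values of named genes kept direction and side of the threshold, 156 lost and 2 gained the call and 5 reversed. For lists these numbers were 1746, 153, 55 and 2. All probe sets with a symbol moved nothing, since each symbol has 1 probe set, and gave no value. Where a value moved, the cause was not tested unless the setting itself leaves out genes or arrays. Dim genes limit what arrays can show, and genes above the median of all probe sets gave 124 calls in tibialis anterior cohort 4, 97 in diaphragm cohort 1 and 184 in cohort 4, with a correlation of 0.368 between the muscles. Trended and robust variances gave 33 in diaphragm cohort 1. A further quantile normalization gave 1 cohort difference in the tibialis anterior and 30 calls in diaphragm cohort 4. Array weights gave 2648, 1035 and 203 in tibialis anterior cohorts 1, 3 and 4 and 30 cohort differences, 1158, 1053, 468 and 181 in diaphragm cohorts 1 to 4 and 3 cohort differences, and 2690 for the difference between the muscles. At least 1.5-fold passed 420 in the tibialis anterior, 1070 in its cohort 3, 485 in the diaphragm, 546 for the difference and 2152 between sham muscles. Spearman's correlation was 0.226. With the cohort as replicate 1122 and 1018 passed in the tibialis anterior and diaphragm. An estimated correlation left 5, 3, 9 and 8 lists in the tibialis anterior, the diaphragm, their difference and the sham muscles. Without cohort 1 the counts were 1426, 1501 and 531 (difference) and the correlation 0.30, and without cohort 2 1699 (diaphragm), 705 and 0.353. Without cohorts 3 and 4 the correlation was 0.259 and 0.271. With hepatocyte transcripts as a covariate, 176, 1004 and 145 genes passed in diaphragm cohorts 1, 2 and 4, with 3 cohort differences, and cohort 3 had 156 higher and 211 lower, against 140 and 106. Without the arrays holding them 654 passed in the diaphragm, 515 for the difference and 4366 between sham muscles. The upper quartile gave 110 in tibialis anterior cohort 4, 77, 379 and 369 in diaphragm cohorts 1, 3 and 4, and limma found 0 cohort differences in the tibialis anterior (2005 unadjusted). With tendon transcripts limma called 0 genes in the tibialis anterior (1073 unadjusted), 0 in cohort 1 (821) and cohort 4 (946) and 0 cohort differences (1708), 99 in cohort 3 and 9 lists. Chad 0.591 (in the covariate), Fmod 0.138, Bnip3 -0.264, Perm1 0.208 and Igf1 0.041 reversed without passing (adjusted p = 0.999 each), as did matrix proteases (adjusted p = 0.681) and glycolysis (adjusted p = 0.0726). Without the 3 arrays that stood apart, 2691 genes and 20 lists passed in the tibialis anterior.

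With each array left out, list calls were lost for slow sarcomere genes in the tibialis anterior (4 fits), adipocyte (14), erythroid (8), fast (2) and slow sarcomere (1) genes in the diaphragm and pericytes in the difference (4). Counts ran from 2522 to 3362 in the tibialis anterior, 2430 to 3047 in the diaphragm, 1253 to 1731 for the difference and 8358 to 9675 between sham muscles, lists from 20 to 22, 19 to 25, 21 to 25 and 25 to 27, and the correlation from 0.284 to 0.331. Tibialis anterior cohort 1 ran from 211 to 932: without sham replicates 1, 2 and 3 of cohort 1 280, 221 and 299, PDX replicates 2 and 3 of cohort 1 211 and 212, and PDX replicate 1 of cohort 3 932. Cohort 2 ran from 0 to 5, with 1 and 5 without PDX replicates 2 and 3 of cohort 2. Cohort 3 ran from 1119 to 2251, with 1119 and 1137 without sham replicates 2 and 3 of cohort 3. Cohort 4 ran from 15 to 173: 108 without PDX replicate 1 of cohort 2, 173 without PDX replicate 1 of cohort 3, 19, 16 and 21 without sham replicates 1, 2 and 3 and 16 and 15 without PDX replicates 1 and 2 of cohort 4. Cohort differences in the tibialis anterior ran from 0 to 6: 6 without PDX replicate 1 or 4 of cohort 3, 1 without sham replicate 2 of cohort 2, PDX replicate 2 of cohort 3 or PDX replicate 1 of cohort 1. They were 0 by limma (1454 to 2060 unadjusted) without sham replicate 1 or 3 or PDX replicate 1, 3 or 5 of cohort 2, sham replicate 1 or 3 or PDX replicate 3 of cohort 3, any array of cohort 4, or replicate 2 or 3 of either group of cohort 1. Diaphragm cohort 1 ran from 0 to 114: 51, 46 and 114 without PDX replicates 1, 4 and 5 of cohort 2, 20, 28 and 28 without PDX replicates 1, 3 and 4 of cohort 3, 104 and 38 without PDX replicates 2 and 3 of cohort 4, 1, 0 (1702 unadjusted) and 2 without sham replicates 1, 2 and 3 and 57 and 0 (1441 unadjusted) without PDX replicates 1 and 2 of cohort 1. Cohort 2 ran from 143 to 953: 143, 296 and 185 without sham replicates 1, 2 and 3 and 365, 953 and 279 without PDX replicates 1, 4 and 5 of cohort 2. Cohort 3 ran from 61 to 323: 70, 107 and 61 without sham replicates 1, 2 and 3 and 135 and 130 without PDX replicates 1 and 2 of cohort 3. Cohort 4 ran from 4 to 231: 136 and 59 without PDX replicates 1 and 3 of cohort 2, 59 without PDX replicate 2 of cohort 3, 4, 4 and 49 without sham replicates 1, 2 and 3 and 4, 21 and 231 without PDX replicates 2, 3 and 4 of cohort 4, and 54, 47, 57 and 58 without sham replicates 1 and 2 and PDX replicates 1 and 3 of cohort 1. Cohort differences in the diaphragm ran from 1 to 7: 2 without sham or PDX replicate 2 of cohort 2, PDX replicate 5 of cohort 3 or PDX replicate 3 of cohort 1, 6 and 7 without PDX replicates 1 and 2 of cohort 4 and 5 without sham replicate 3 of cohort 1.

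With the replicate number as a random block, 2854 genes passed in the tibialis anterior, 3002 in the diaphragm, 1491 for the difference and 9288 between sham muscles, and no count moved by over 1.5 times. Correlations of the deviations of equally numbered arrays of both muscles ran from -0.19 to 0.31 over 29 pairs, 7 were above 0.1, and 14 arrays correlated best with their own number (8 by chance), a hint from the data. As not every correlation was above 0.1, the fits did not pair the samples.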

Other observations

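Tests on other splits of the samples were all chosen only after the counts were seen. Clock genes did not pass as a list in the tibialis anterior (6 higher and 4 lower of 19, also adjusted over the list alone, adjusted p = 0.0841), but single members moved there: Nfil3 rose by 0.95, Cry2 by 0.92 and Per1 by 0.82, and Dbp had a difference of -0.76. With the cohort as the replicate the calls of Cry2, Per1 and Dbp were lost, that of Dbp also without cohort 1, and the Cry2 effect in cohort 3 exceeded the others by 1.76. In the diaphragm (4 higher and 3 lower of 19, also adjusted over the list alone, adjusted p = 0.105) Per2 rose by 0.86 and Per1 by 0.76, while Arntl (-0.96) and Nr1d1 (-0.95) fell. The call of Nr1d1 was lost without cohort 1, without the arrays with hepatocyte transcripts and with the cohort as the replicate, that of Per1 in the last setting and without cohort 3, and that of Arntl without cohort 2 and without cohort 3. Of 8 erythroid markers, 4 rose and 0 fell in the tibialis anterior (5 and 0 adjusted over the list alone, median 0.41, adjusted p = 0.000403, 0.0773 with an estimated correlation), with the globin gene Hbb-b1 at 1.24 (2.36-fold, SE 0.25), a call lost without cohort 1. In the diaphragm 2 rose and 0 fell (2 and 0 adjusted over the list alone, median 0.346, adjusted p = 0.0374, 0.45 with an estimated correlation), but over cohorts 2 to 4 without the arrays with hepatocyte transcripts the median was -0.0598 (adjusted p = 0.876). The call of Slc4a1 (0.77, adjusted p = 0.0369) was lost in 13 of 29 fits that left out 1 array.

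Of 21 endothelial markers, 6 were higher and 1 lower in the tibialis anterior (6 and 2 adjusted over the list alone, adjusted p = 0.117), with Vwf at 0.42. In the diaphragm 3 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.0989, adjusted p = 0.00538, 0.457 with an estimated correlation), with Plvap at 1.09 and Vwf at 0.52, a call lost with the cohort as the replicate. Insulin and IGF signalling genes did not pass in the tibialis anterior (8 higher and 4 lower of 24, 8 and 5 adjusted over the list alone, adjusted p = 0.31) or the diaphragm (6 and 3, 7 and 5 adjusted over the list alone, adjusted p = 0.185). Igfbp3, a carrier of IGF, rose by 1.26 and Igfbp5 had a difference of -1.08 in the tibialis anterior, and Igfbp4 rose by 0.60 in the diaphragm, a call lost without cohort 1, cohort 2 or the arrays with hepatocyte transcripts.

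Other splits of the same arrays were fitted, at most 100 per result, with the real split counted. Chance was excluded for the calls in the tibialis anterior (1 of 100 splits as large, 2979 against 324 in the highest other split), the diaphragm (1 of 100, 2892 against 3; the permutations of both muscles together gave up to 1713 in the tibialis anterior alone and 644 in the diaphragm alone), the difference (1 of 100, 1468 against 12) and the sham muscles (1 of 100, 9210 against 720). List counts exceeded all other splits only in the tibialis anterior (1 of 100, 21 against 19). Chance stays open for the difference (3 of 100, 22 against 22) and the sham muscles (2 of 100, 25 against 27). So it does for the diaphragm (9 of 100, 23 against 26). For the cohort differences chance stays open. Another split gave more in the tibialis anterior (3 of 100, 3 against 68) and the diaphragm (4 of 100, 1 against 4). The split with 68 points to an untested structure of the samples. Within cohorts of the tibialis anterior chance was excluded for cohort 4 (1 of 35, 70 against 13), while in cohort 3 another split gave more genes (2 of 56, 1845 against 1888). The count of 0 in cohort 2 by limma (1265 unadjusted, against 1) tests nothing, since 56 of 56 splits are then as large. In the diaphragm chance was excluded for cohort 2 (1 of 56, 624 against 411) and cohort 4 (1 of 35, 89 against 58) and not for cohort 3 (4 of 56, 246 against 756). Splits of cohort 1 are too few for a share under 0.05, with 570 against 1 in the tibialis anterior (1 of 10) and 8 against 13 in the diaphragm (2 of 10).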
